A study of Ciona robusta with 2 samples.

How the data were processed

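Single-cell libraries were made by the submitters from *Ciona robusta* blood with version 3.1 of the 3′ droplet chemistry, 1 library in artificial seawater diluted with water and 1 in 0.7 M D-mannitol in phosphate-buffered saline, per the labels' protocols. Cells were spun down in the cold and resuspended at 1000 to 2000 cells per microlitre, per the same protocols. Cell Ranger 6.1.2 is named in the submitters' processing notes. The genome build and gene annotation are not given in the sources used here. The deposited matrix of the mannitol library holds whole-number UMI counts per gene and barcode, not normalised and not filtered for cells. For the seawater library only the barcode and gene lists were used here. Each sample was placed in its group by its treatment label, and 0 columns of values were left without a sample.

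The files pair no gene name with an identifier. Of the 18827 identifiers, 18788 begin with KY21 and 39 with ENSCING, and 0 matched the RefSeq gene table supplied as a reference. The 14 cell type marker lists and 16 gene lists fixed before the data were examined, which need names or product descriptions, therefore matched 0 identifiers, and no result by list, cell type or function could be given. Genes appear by identifier only, with at most 2 higher and 2 lower per comparison. The rule for them, fixed in advance, took the 10 genes with the most UMIs in cells, the 10 highest and 10 lowest ratios of cells to background among genes with at least 100 UMIs together and 10 in each, and for each cluster the 5 genes with the highest ratio to the next cluster among genes with at least 100 UMIs and a UMI in at least 25% of cells. The most abundant gene of each cluster and the comparison with empty droplets were added after values were seen.

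The cell threshold was placed at the valley of the UMI-weighted histogram of log10 UMIs per barcode, in bins of 0.05 smoothed over 5 bins, which gave 473 UMIs. Background barcodes were those with 1 to 47 UMIs, the upper end being the threshold divided by 10. Doublets were scored with Scrublet as implemented in scanpy 1.11.5 at an expected rate of 6%. It called 0 of 7531 cells at a score threshold of 0.654, so the caller did not work on these data, no doublet was removed, and clusters can hold some. Counts were scaled to 10000 per cell and log-transformed with 1 added, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 gave the clusters, with seed 0 (igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1). These are the steps fixed in advance. The cells had first been clustered with genes also z-scored, a step outside that plan, which gave 26 clusters and is kept as an alternative. Genes per cell were compared after thinning each cell to 473 UMIs, which left out no cell.

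Shares have exact binomial (Clopper-Pearson) 95% intervals, and ratios of 2 counts have exact conditional binomial 95% intervals. Both cover counting error only. Genes specific to a cluster had at least 100 UMIs in it and at least 4-fold the CPM of every other cluster. The profile of empty droplets was fitted as a non-negative mixture of cluster profiles, with genes weighted by the inverse square root of CPM plus 1, and 100 Poisson resamples gave the interval of the fit. Levels of cluster genes were taken from the part of a random binomial division of the counts into 2 parts that was not used for clustering, but the genes were chosen on all counts. The fit and the specific genes were compared only for clusters with at least 3 specific genes.

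The steps were tested on simulated data. For 2 simulated cell types that differed in 200 genes at the depths of the real cells, over 18827 genes, the interval held the true fold for 95.0% of 4-fold and 100.0% of 2-fold genes. Cells were pooled there by their true type and varied by counting error only, so this does not test folds between inferred clusters. The clustering as planned did not recover the 2 types as 2 clusters: it gave 4, with 98.5% of cells in a cluster led by their own type (adjusted Rand index 0.50). Cells of a type differed only in depth and counting error, and the depths of the 4 clusters were not compared. After thinning to 473 UMIs it gave 2 clusters with 95.2% of cells in the right one, and this version is given as an alternative. The threshold recovered 100.0% of simulated cells. These all had at least 1000 UMIs and did not overlap the simulated empty droplets in depth. The result therefore does not test the call for the 22.9% of real cells below 1000 UMIs. The mixture recovered simulated shares within 1.23 percentage points when simulated from the same profiles that were then fitted. This is not its error on the real empty droplets, where specific genes gave other shares. Alternatives fixed in advance changed the threshold, the background, the clustering settings and the doublet handling. Thinning, z-scoring, the range of empty droplets, the shares from specific genes, and leaving out the cells with the highest doublet scores were added after the data were seen.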

Results

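The series measured messenger RNA in single circulating blood cells of wild-caught adult *Ciona robusta*, a sea squirt, with droplet-based 3′ sequencing in which each captured molecule carries a cell barcode and a unique molecular identifier (UMI). Blood pooled from several animals was divided between 2 tubes, and 1 library was made from each. Cells of the seawater library were resuspended in calcium- and magnesium-free artificial seawater buffered with HEPES (5 mM, at pH 7.4; sodium chloride 0.5 M, potassium chloride 9 mM) and diluted with water before encapsulation. Cells of the mannitol library were resuspended in 0.7 M D-mannitol in phosphate-buffered saline, which also served as the diluent. The design asks whether a low-salt buffer of high osmolarity suits marine cells better than diluted seawater. Counts per gene were analysed here for the mannitol library, and the lists of barcodes and of genes for both. With 1 library per buffer, no test between buffers was possible, and every interval given covers counting error only. The mannitol counts summed to 55568330 UMIs over 15583 of the 18827 listed genes.

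The seawater library listed 1.83 times as many barcodes as the mannitol library, 2890554 against 1578112. Both lists held 1216115 barcodes in common, which were 77.1% of the mannitol list and 42.1% of the seawater list. The mannitol list included 348931 barcodes without a UMI, 22.1% of the total. The share of mannitol barcodes that the seawater library also listed was 76.7% (exact binomial 95% interval 76.6 to 76.8) at 1 UMI and 82.9% (82.8 to 83.1) at 2 to 9 UMIs. It was 87.2% (87.0 to 87.5) from 100 to 472 UMIs and 87.6% (86.9 to 88.4) in barcodes called as cells, so cells and the deeper empty droplets were not distinguishable in this share. The lists carry no UMI numbers for the seawater library, and cell number, depth and gene detection were not compared between buffers.

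The mannitol library held 7531 cell barcodes, with a median of 2834 UMIs (interquartile range over cells 1072 to 7524) and 981 genes (517.0 to 1726). Cell barcodes contained 72.8% of all UMIs. Depth was wide: 1383 cells (18.4%) had at least 10000 UMIs and 1723 (22.9%) had fewer than 1000. Cells and empty droplets formed separate modes, and the threshold of 473 UMIs lay in the valley between them. Empty droplets of 100 to 300 UMIs, a range chosen after the data were seen, numbered 62921, had a median of 199 UMIs and held 22.3% of the UMIs. A fixed threshold of 250 UMIs gave 15012 cell barcodes, and one set from the 99th percentile of the deepest barcodes, 3442 UMIs, gave 3403.

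**Figure D1:**
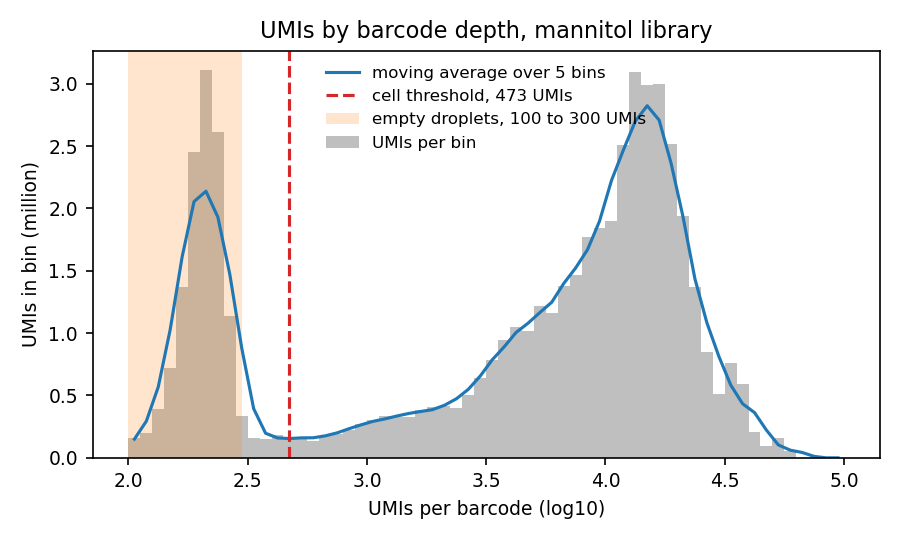
UMIs of the mannitol library by barcode depth, in bins of 0.05 on the log10 scale (bars) with their moving average over 5 bins (line). The dashed line marks the threshold of 473 UMIs, and the shaded range from 100 to 300 UMIs holds the empty droplets.

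Empty droplets were dominated by a few genes that were less abundant in cells. KY21.Chr12.265 reached 83282 CPM (UMIs scaled to a total of 1000000) in empty droplets and 14756 CPM in cells, 5.64-fold higher outside cells (exact conditional 95% interval 5.63 to 5.66). KY21.Chr6.143 reached 42095 CPM in empty droplets against 10173 CPM in cells, 4.14-fold higher (4.12 to 4.15). Both were among the 10 genes with the most UMIs in cells, of which 6 were higher in empty droplets and 4 were lower. The 2 most abundant genes of cells were among the 4: KY21.Chr7.170 stood at 20749 CPM in cells and 5796 CPM in empty droplets, and ENSCING00000025213 at 15737 against 3759 CPM. The 10 leading genes took 33.8% of UMIs in empty droplets and 12.2% in cells, and 4 genes were on both lists.

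In the comparison fixed before the data were examined, cells were set against barcodes of 1 to 47 UMIs. Over 7087 genes with enough counts, the median log2 ratio of cells to this background was 0.48, and the 10th and 90th percentiles were -0.12 and 1.09. The genes lowest in cells were KY21.Chr14.605, 8.63-fold higher in background (7.68 to 9.69; 259.2 CPM in background), and KY21.UAContig49.10, 8.02-fold higher (5.71 to 11.1; 32.9 CPM in background). The size of these differences depended on the background: in empty droplets they were 25.8-fold (24.3 to 27.4) and 20.3-fold (17.2 to 24.0), and their log2 ratios of -3.11 and -3.00 became -1.35 and -1.89 with background of 1 to 10 UMIs. With the threshold at 250 UMIs, which also lowers the background limit, they were -0.64 and -1.14, and at 1000 UMIs -6.22 and -5.83. The genes highest in cells were KY21.Chr4.815, 5.69-fold over background (3.17 to 11.4), and KY21.UAContig44.7, 5.02-fold (3.09 to 8.80), from 11 and 16 background UMIs. Over empty droplets they were 3.16-fold (2.69 to 3.73) and 4.67-fold (3.95 to 5.58) higher in cells. The 39 genes with ENSCING identifiers together made up 2.65% of UMIs in cells, 1.20% in background and 0.871% in empty droplets. Barcodes of 1 to 3 UMIs supplied 94.0% of the background UMIs, so this background did not sample the empty-droplet mode.

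The 7531 cells fell into 21 clusters of 24 to 1316 cells, which are numbered by size and left unnamed because none of the fixed marker lists could be matched to the identifiers. Cluster 1 held 17.5% of cells, cluster 2 held 11.2% and cluster 3 held 8.29%. Median depth ran from 805 UMIs in cluster 3 to 13086 in cluster 2, so that cluster 2 supplied 26.9% of all UMIs in cells. At 473 UMIs per cell, the median number of genes ranged from 108 in cluster 17 to 334 in cluster 14. With counts divided at random into 2 parts, the clusters of 1 part matched 20 of the 21 clusters (Jaccard index at least 0.5), the exception being cluster 17. Clusters 11 and 17, and clusters 5 and 8, fell into the same cluster when every cell was first thinned to 473 UMIs, and 50% of the cells of cluster 21 joined the one that held 96.7% of cluster 2. In simulated cells of 2 types the clustering made 4 clusters, although cells of a type differed only in depth and counting error, so the number of clusters is not a number of cell types.

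Several clusters were marked by single genes at very high levels, given here from the part of the counts that was not used to form the clusters, although the genes were chosen on all counts. Levels and folds here and for the larger clusters below were not corrected for RNA from outside the cells. In the 37 cells of cluster 19, KY21.Chr3.1436 stood at 307216 CPM, and over all counts it was 30.6% of the cluster's UMIs. KY21.Chr10.989 stood at 484608 CPM in the match to cluster 20, a cluster of 32 cells, 279.8-fold over the next cluster (253.8 to 309.2), and KY21.Chr2.890 at 289548 CPM, 115.4-fold (111.3 to 119.6). In cluster 18, KY21.Chr5.313 was 483.4-fold over the next cluster (287.9 to 884.7) and KY21.Chr1.1090 was 557.1-fold (352.3 to 940.3). Cluster 14 was set apart by KY21.Chr12.617, at 28836 CPM and 391.5-fold over the next cluster (304.9 to 511.2), and by KY21.Chr13.78, at 33277 CPM and 94.5-fold (81.3 to 110.3).

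Among larger clusters, cluster 4 was led by KY21.Chr1.1264, at 81741 CPM and 77.7-fold over the next cluster (68.1 to 89.1), and by KY21.Chr12.243, 47.4-fold (38.1 to 59.8). Cluster 6 was led by KY21.Chr4.71, 39.4-fold over the next cluster (33.0 to 47.4), and KY21.Chr11.714, 35.7-fold (27.8 to 46.6). Clusters 4 and 6 shared KY21.Chr7.170 as their most abundant gene, with 9.24% and 14.8% of their UMIs. In cluster 7, KY21.Chr7.795 was 60.5-fold (40.5 to 94.6) and KY21.Chr8.506 62.2-fold (27.7 to 173.2) over the next cluster. In cluster 9, KY21.Chr2.1414 was 64.6-fold (50.2 to 84.4) and KY21.Chr4.1179 53.9-fold (43.5 to 67.3). Cluster 1 was less distinct: KY21.Chr12.537, its gene with the higher level among the 2 leading ones, was 4.48-fold over the next cluster (4.25 to 4.73). Clusters 5 and 8 had no gene of at least 100 UMIs at 4-fold or more over every other cluster, and their profiles correlated at r = 0.97 across genes, which are not independent replicates.

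**Figure D2:**
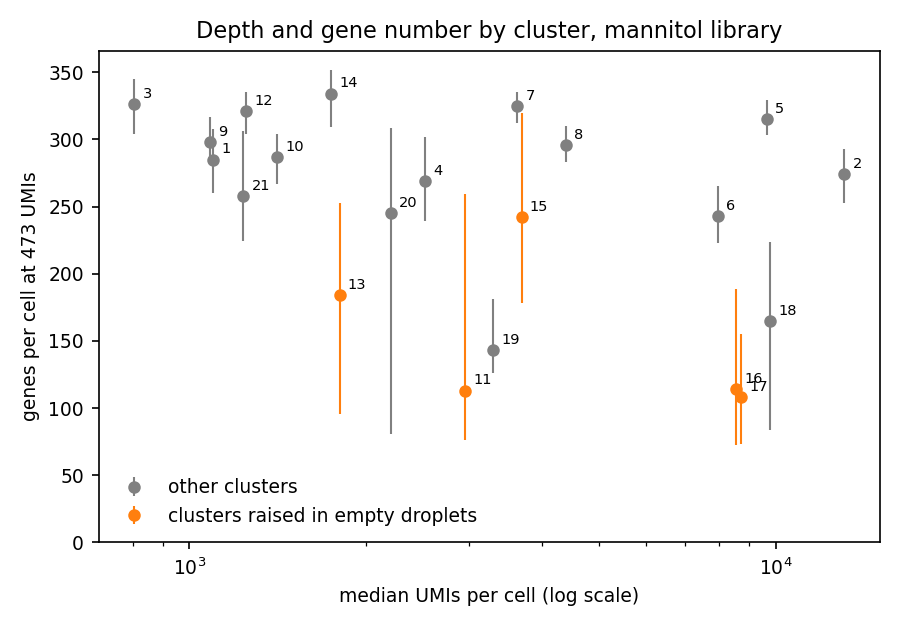
Median UMIs per cell (log scale) and median genes per cell at 473 UMIs for the 21 numbered clusters of the mannitol library, with bars for the interquartile range over cells. The 5 clusters raised in empty droplets are in orange, and 3 of them, numbers 11, 16 and 17, have the fewest genes, with medians of 113, 114 and 108.

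Most RNA of empty droplets was assigned by a fit to a few of these clusters. Fitted as a mixture of the cluster profiles, 71.7% of it was assigned to clusters 11, 13, 15, 16 and 17, which held 12.5% of cells and 18.2% of the UMIs in cells. Cluster 11 alone was given 25.4%, cluster 17 17.9% and cluster 16 15%. After thinning, 97.6% of cluster 11 and 98.3% of cluster 17 fell into the same cluster, so the division of RNA between these 2 is uncertain. Genes high in both are also left out of their specific genes. These 5 clusters were raised at least 1.5-fold both in the fit and by their own specific genes, but the sizes differed for 3 of them. The fitted share was 6.56-fold the share of UMIs in cells for cluster 11, 5.08-fold for cluster 17 and 3.78-fold for cluster 16, while their specific genes were more abundant in empty droplets than in cells by 3.17-fold, 3.15-fold and 1.76-fold. For clusters 13 and 15 the fit gave 2.15-fold and 1.82-fold and the specific genes 2.26-fold and 1.85-fold. Shares of UMIs in cells multiplied by the folds of the specific genes come to 44.2% for the 5 clusters, so the size of their share depends on the method. The fit divides all of the RNA among the clusters, while these products need not add up to all of it and are missing for clusters 5, 8 and 20. The values of 71.7% and 44.2% are therefore not on the same scale. Clusters 1 and 9 were raised in the fit alone, 1.53-fold and 2.48-fold, with their specific genes at 1.20-fold and 1.25-fold. Cluster 20 was raised 5.16-fold in the fit and left out of the 5 because it had only 2 specific genes, fewer than the 3 required, although these made up 2.23% of UMIs in empty droplets and 0.482% in cells. Clusters 2 and 5, with 26.9% and 14.1% of the UMIs in cells, were given 0% each by the fit, and 8 clusters with 58.3% of these UMIs were given under 1% each. The profile of cluster 5 correlated at r = 0.97 with that of cluster 8, which was given 3.87%. The fit may place RNA of both on 1 of them, and cluster 5 had no specific genes, so its 0% does not show that its RNA was absent. Specific genes gave less extreme values: those of clusters 2 and 6 stood at 0.178-fold and 0.319-fold in empty droplets, which corresponds to shares of 4.78% and 3.21%, where the fit gave 0% and 0.794%. The 7 of these 8 clusters with specific genes come to 10% in this way. Clusters 11, 16 and 17 had the fewest genes per cell once cells were thinned to 473 UMIs, and their 10 leading genes took 67.7%, 66.7% and 61.6% of their UMIs. KY21.Chr12.265 was the most abundant gene of clusters 11 and 17, with 16.3% and 13% of their UMIs, and KY21.Chr1.500 was that of cluster 16, with 19.5%. KY21.Chr1.500 was also that of cluster 3, with 9.13%, a cluster that was lower in empty droplets (0.574-fold in the fit and 0.636-fold by specific genes). The mixture and the choice of empty droplets were set after the data were seen, and with barcodes of 1 to 47 UMIs the 5 clusters were given 47.7% and cluster 2 was given 9.83%. In those barcodes the specific genes of clusters 11, 13, 15, 16 and 17 were 2.00-fold, 1.43-fold, 1.60-fold, 1.16-fold and 1.93-fold over cells. Clusters 13 and 16 thus fell below 1.5-fold there. Cells were also clustered again without the 6% with the highest doublet scores. The best match to cluster 15 (Jaccard index 0.59) then held 1.27% of cells, against 2.27%, and that to cluster 16 (0.58) held 3.14%, against 1.83%. The clusters were redrawn, so these values do not give a share of doublets.

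**Figure D3:**
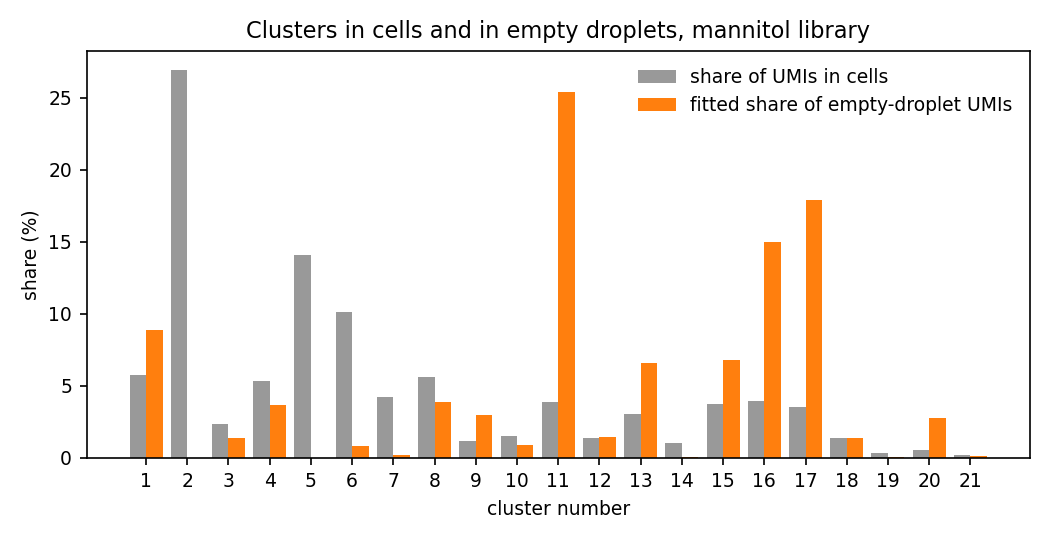
Share of UMIs in cells (grey, percent) and fitted share of empty-droplet UMIs (orange, percent) for each of the 21 clusters of the mannitol library. Clusters 11, 16 and 17 have the highest fitted shares, 25.4%, 15% and 17.9%, and cluster 2, with 26.9% of the UMIs in cells, is fitted at 0%, where its specific genes correspond to 4.78%.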

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

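Thinning, z-scoring, empty droplets, other backgrounds for the mixture, the share from specific genes and removal of high doublet scores were chosen after the data were seen. No paired analysis was possible because each buffer had 1 library and no test was made. Cell number, depth and share of UMIs moved with the threshold: at 250 UMIs there were 15012 cells with a median of 477 UMIs and 265 genes and 76.7% of UMIs. At 500 UMIs the share was 72.7%. At 1000 UMIs the medians were 4299 UMIs and 1299 genes, with 70.6% of UMIs. At the threshold from the 99th percentile, 3442 UMIs, 3403 cells had medians of 8328 UMIs and 1820 genes and held 62.4% of UMIs. Fewer shallow barcodes by construction raise these medians. Counting only mannitol barcodes with at least 1 UMI, 78.6% were shared with the seawater list, against 77.1%. The number of clusters was 21 and ranged from 18 to 27 over all the settings run, within 1.5 times the main number, and was 26 with z-scoring and 18 after thinning.

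Shares of cells per cluster are those of the best match after clustering again, not of the same cells. They depended on the setting, and apart from the loss of shallow cells at 1000 UMIs the cause was not tested. At 1000 UMIs clusters 1, 3 and 15 held 7.37%, 5.27% and 2.63%. Without the highest doublet scores, clusters 1, 3, 15 and 16 held 18.4%, 7.35%, 1.27% and 3.14%. After thinning, clusters 1, 2, 3, 11 and 16 held 14.9%, 12.6%, 10.8%, 5.72% and 2.76%. With z-scoring, clusters 1, 3 and 13 held 12%, 7.66% and 3.89%. No cluster matched (Jaccard index under 0.5) cluster 2 or 16 at 1000 UMIs, 2 or 15 with z-scoring, or 15 or 17 after thinning, so these have no value. The fit gave the 5 clusters 71.7% of RNA in empty droplets and 47.7% with barcodes of 1 to 47 UMIs. With those up to 0.5 of the threshold it gave 66.9%. Specific genes gave 44.2%, not on the same scale. After thinning, the 4 clusters made up mainly of cells of these 5 were given 73.0%, which is not a value for the same clusters. Results by gene list have no value because no list matched an identifier. Of the ratios of cells to background for 16 genes, 46 values under other settings lay inside the counting interval, 68 moved outside it, and 4 changed the sign of a ratio whose interval excluded 1. All 4 belonged to KY21.Chr1.1866, whose log2 ratio of 0.07 became -0.05 with background up to 0.5 of the threshold and -0.05 with empty droplets, -0.03 at 1000 UMIs and -0.22 at 3442 UMIs; the cause was not tested. Of 39 cluster gene folds, 11 moved outside their counting interval in the held-out counts, among them KY21.Chr13.78 in cluster 14 from 322.1 to 94.5 and KY21.Chr2.54 in cluster 2 from 3.64 to 1.43. The genes had been chosen for high folds on all counts, so that a fold stayed above 1 is no independent check.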

Other observations

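All tests in this part were chosen after the results they bear on were seen, and no biological explanation was tested, since the design gives only the buffer as a group. The 39 ENSCING genes made up 5.87% of UMIs in cluster 9 and 4.93% in cluster 1, against 0.893% in cluster 13 and 0.965% in cluster 11. Of these genes, 14 had at least 1000 UMIs in the library. Only 3 genes were at least 2-fold higher in empty droplets than in every cluster.

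RNA of clusters 11, 13, 15, 16 and 17 was a larger share of UMIs in empty droplets than in cells. Their profiles were compared with that of empty droplets, to ask whether these clusters are droplets of evenly mixed free RNA alone. Of the 100 leading genes of empty droplets, a median of 40% lay within 2-fold of the empty-droplet level in the 5 clusters (9.00% to 46.0%). Other clusters were not compared in this way, and free RNA that is not evenly mixed was not tested. Small cells below the threshold would bunch a cluster's specific genes in few droplets, and for clusters 13 and 15 the bunching was 14.5% and 32.2% of that expected if cells filling 25% of a droplet's UMIs held all of these UMIs, which argues against cells of that size or larger as the whole source. For clusters 11, 16 and 17 it was 5.66% (95% interval over resampled droplets 4.75 to 6.69), 14.8% (13.3 to 16.3) and 22.2% (20.4 to 23.9) of that expected from cells filling whole droplets, which argues against these as the whole source. On the scale of cells filling 25% of a droplet it was 57.9%, 81.6% and 232.7% of a small expected excess. The lower ends of the 95% intervals were 48.6%, 73.5% and 213.8%. Some RNA of clusters 11, 16 and 17 was therefore bunched, which argues against evenly mixed free RNA as its whole source. For cluster 17 the bunching was above all of that expected from cells of that size. How much of this RNA came from such cells cannot be told from these values. The scale of cells filling 25% of a droplet was set after the variances were seen. It replaced a first bound of 2 on the variance over binomial, which clusters 13 and 15 had passed at 5.00 and 6.13. The reading for these clusters therefore depends on the scale. Both values are above the binomial expectation that evenly mixed free RNA would give, so some of this RNA was bunched. Preferential loss of RNA from cells of these clusters may contribute, and it stays open and untested.

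Genes specific to 1 cluster often had consecutive identifiers: the 19 lists held 58 such pairs, 17 of them in cluster 15 and 12 in cluster 13. In 10000 random draws of lists of the same sizes, 0 held as many, the mean was 2.20 and the highest was 9, so a random order of the identifiers does not account for them. If all counts of 1 gene were reads of its neighbour, the ratio of the pair would be even in all cells. In 30 of 55 testable pairs it differed between the cluster and other cells beyond the 95% counting interval, which leaves out variation between cells. These differences went from log2 0.10 (KY21.Chr1.267 and KY21.Chr1.268) to -3.67 (KY21.Chr13.84 and KY21.Chr13.85). Reads shared in part could also change the ratio, so this count does not exclude them. Counts in other cells were not corrected for RNA from outside the cells, so they do not show that other cells express these genes. For the other 25 pairs the interval included no difference. Reads of 1 gene counted for its neighbour, shared expression and RNA of the cluster taken up from outside the cells cannot be told apart there. Whether the neighbours are gene copies could not be tested without sequences, so common regulation or duplication may be involved only as a hypothesis.

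Fitted as a mixture of cells and empty droplets only, the RNA of barcodes of 1 to 47 UMIs was given 47% cells and 53.0% empty droplets. The fit offered no other profile, so it could only place these barcodes between them. Some genes lay outside both: KY21.Chr4.815 stood at 7.39 CPM there, 42.1 in cells and 13.3 in empty droplets. KY21.Chr1.436 stood at 128.9 CPM there, 32.7 in cells and 36.8 in empty droplets. Misreading of a single base in cell barcodes could place cell RNA there. Listed barcodes 1 mismatch from a cell barcode held 1.03% (1.02 to 1.05) of the background UMIs and were 0.357% of the background barcodes. Single-base misreads that stayed in these barcodes can supply at most this share, below the 47% fitted as cells, which argues against them as the main source. Whether the processing corrected or dropped other misreads was not tested, so the count does not measure how often misreading occurred. Other sources of these barcodes were not tested.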
